A study of Mus musculus with 4 samples.

How the data were processed

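The series profiled CD8 T cells that infiltrated hepatocellular carcinoma in mice and were sorted by flow cytometry into JAML-positive and JAML-negative cells. JAML, the junctional adhesion molecule-like protein, is a cell surface receptor of the immunoglobulin superfamily. Per the labels' protocols the cells were of wild-type genotype, RNA was taken with a column kit, and libraries were made from total RNA with a SMARTER mRNA-Seq kit. There were 4 libraries in 2 groups, with replicates A and B in each group. The labels do not say whether A and B were separate animals, pools or sorts, so p-values here measure only the spread between these libraries, which may be technical.

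The authors deposited a table of read counts per gene for the whole series, with gene symbols, Entrez identifiers and pathway annotation. The values are whole numbers with a different total in each library, and no further normalization is recorded for them. The build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program, its treatment of strand and of reads with several matches, and the annotation version are not given in the sources used here. The table holds 14934 genes, of which 13118 are marked protein-coding and 1816 non-coding, and 0 of them have a count of 0 in all 4 libraries. Library totals were 27819178 and 27530187 counts for JAML-negative replicates A and B, and 27717149 and 30569728 for JAML-positive replicates A and B. A total of 3 counts, taken as the floor for a gene without counts, corresponds to 0.098 to 0.109 counts per 1000000 (CPM). Reads carry no molecular identifiers, so floors and counting intervals cover counting error only.

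Genes were placed on GRCm38.p6 with RefSeq coordinates by Entrez identifier, which matched 14681 genes (98.3%). Transcript length and GC content were those of the longest GENCODE transcript, which 13795 genes have. Exons of 3 of the genes named here, Fcer2a not checked, overlap exons of another gene in the table, each on the opposite strand. They are Jaml with Gm10684 (15.5% of the exonic bases of Jaml), Gga3 with Mrps7 (3.3%) and Rpl35 with Wdr38 (0.3%). Counts of histocompatibility, Klra, haemoglobin and ribosomal protein genes are uncertain where reads match several family members or pseudogenes.

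Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 11563. Libraries were scaled with TMM factors, dispersions were estimated robustly, and the quasi-likelihood test compared the 2 groups with no covariate. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error (SE) was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. The 95% intervals from edgeR use this SE with a t quantile. CPM are given on the TMM scale as mean ± SD. For a gene without counts in a group the fold is a lower bound against 3 counts per library. For a gene with 1 to 3 counts in a group the ratio of summed counts is given with its exact 95% interval. Where a gene's groups are said not to overlap, both libraries of a group lie above both of the other.

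Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with the inter-gene correlation preset at 0.01 and adjustment over 29 lists. Camera asks whether a list moves more than the other tested genes. With an estimated correlation it uses the few residual degrees of freedom of the 4 libraries, so few lists can pass whatever their correlation. The camera p of the cell cycle list went from 3.53e-07 to 0.0276 in that setting, although its estimated correlation (-0.02) lay below the preset 0.01. A list's size is the mean log2 difference of its members, and the direction of a list across alternatives is the sign of that mean. Each list's median fold change was also ranked among 10000 random lists of equal size drawn from 50 bins of abundance. Genes of the random lists were drawn independently, so members that move together were not matched. The comparisons, the lists, the first set of other settings and the rule for named genes were fixed before the data were examined. Of the 30 lists fixed, T cell receptor variable segments matched 0 symbols and was not tested. Mitochondrial genes carry no prefix in the table, so that list was taken as the protein-coding genes of the mitochondrial chromosome, a choice made after the table was seen. Lists of plasmacytoid dendritic cell and plasma cell markers were written after the first results, before their members were looked at. The KEGG and Reactome terms in the deposited annotation with 15 to 300 tested members were tested with camera as well, also a choice made later.

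The rule for named genes took Jaml, Cd8a, Cd8b1, Cd3e and Cd4, then genes past the threshold in each direction or, with none, the 5 with the smallest p in each direction among genes with at least 10 CPM in a group. It left out predicted genes, pseudogenes and antigen receptor segments. Up to 4 members with the smallest p in each list were added, of which the text names a part. Malat1, H2-Aa, Tcf4, Blnk, Cybb and Spib fall outside the rule and were chosen after their values were seen.

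The procedure was tested on 5 simulated data sets of 11563 genes with the libraries' own means, depths and dispersions. In the simulated comparison of JAML-positive with JAML-negative cells, edgeR recovered 5.4% of genes changed 2-fold, 34% of those changed 4-fold and 50.3% of those changed 8-fold. Among genes above 100 CPM the shares were 13.9%, 93.1% and 98.4%. The recovered genes numbered 18, 114 and 166 at 2-fold, 4-fold and 8-fold over the 5 data sets. Against these, edgeR made 29 false calls, a larger share of its calls than the threshold of 0.05 aims at. Camera found 5 of 5 planted lists of 35 genes changed 1.5-fold, all drawn from genes above 30 CPM, and 1.6% of 500 unchanged lists had p under 0.05. Lists of genes near the floor were not simulated. Genes were drawn independently, so the 1.6% does not cover lists whose members move together. In the real data camera's estimated correlation was 0.89 for ribosomal proteins, 0.43 for oxidative phosphorylation and -0.02 for the cell cycle list.

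The settings varied were RLE and upper quartile factors, library totals only, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 5 CPM in 2 libraries, the replicate letter as a block, each library left out in turn, camera with an estimated correlation, and fry. With a library left out, the remaining library of its group is assumed to vary like the other group. A filter on a mean of at least 30 CPM, and removal of each library's trend with transcript length and GC content (natural splines with 4 degrees of freedom), were added after the data were seen. Alternatives for normalized values were not run because the table holds counts.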

Results

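Transcript counts were compared between JAML-positive and JAML-negative CD8 T cells sorted from mouse hepatocellular carcinoma, with 2 libraries per group and 27530187 to 30569728 counts per library. The comparison asks how gene expression differs between tumour-infiltrating CD8 T cells with and without JAML at the surface. Between 12069 and 12527 genes had at least 1 count in a library. Spearman's rho between libraries, across genes, was 0.897 within the JAML-negative pair and 0.912 within the JAML-positive pair, and 0.895 to 0.902 between groups. JAML-positive replicate A stood apart from the other libraries. Ribosomal protein genes took 11.57% of its counts, against 7.14% to 7.95% in the others, and the nuclear RNA Malat1 took 0.07%, against 0.12% to 0.146%.

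Jaml (Entrez 270152, chromosome 9, 45079153 to 45108531, GRCm38) was present at 124 ± 9.89 CPM in JAML-negative and 142 ± 6.53 CPM in JAML-positive cells (SD, n = 2). Its counts were 3693 and 3214 in JAML-negative replicates A and B, and 3638 and 4592 in JAML-positive replicates A and B. The log2 fold change was 0.20 (SE 0.26, edgeR adjusted p = 0.881), and the upper end of its 95% interval was 1.72-fold. The messenger RNA of the sort marker therefore did not separate the groups by this test, although both JAML-positive libraries lay above both JAML-negative libraries in CPM. The group names are those of the labels, and each direction given here rests on them. The titles of the libraries call the JAML-negative group CON and the other group JAML. The names JAML-negative and JAML-positive come from the sample descriptions. Transcripts of the CD8 co-receptor, Cd8a (log2 fold change -0.03, SE 0.19) and Cd8b1 (0.27, SE 0.21), and Cd3e (0.05, SE 0.21) were abundant in all 4 libraries. Cd4, the co-receptor of helper T cells, was also present in every library, at 122 ± 3.15 CPM in JAML-negative and 153 ± 28.0 CPM in JAML-positive cells. None of these passed the test (adjusted p from edgeR between 0.766 and 0.983).

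**Figure D1:**
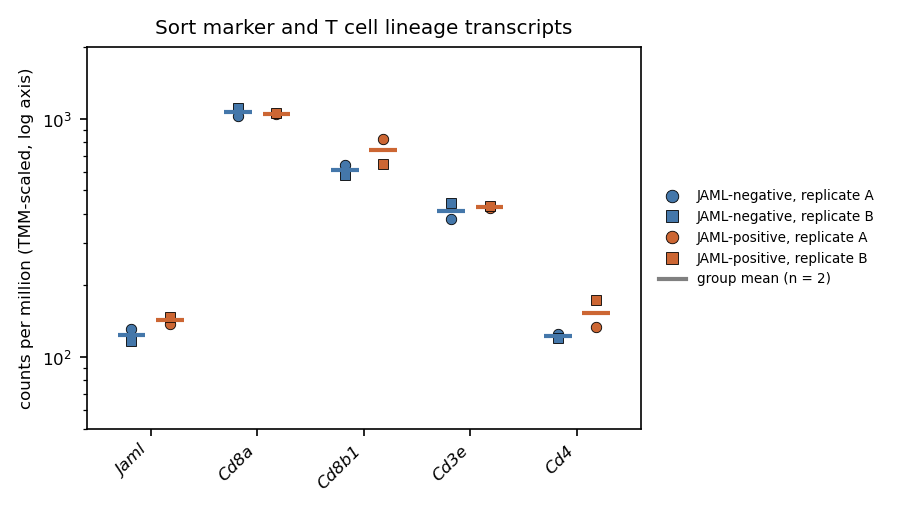
Expression in CPM (log axis) of Jaml, Cd8a, Cd8b1, Cd3e and Cd4 in each library. Circles and squares are replicates A and B, and bars are group means (n = 2). Jaml lay at a mean of 124 CPM in JAML-negative and 142 CPM in JAML-positive cells.

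By camera with a preset correlation, lists of the cell cycle, glycolysis and oxidative phosphorylation had higher values in JAML-positive cells and immediate early genes lower values. None of these 4 lists passed with an estimated correlation (adjusted p = 0.655, 0.688, 0.850 and 0.688), and 0 of their members passed over all genes. Oxidative phosphorylation did not pass with length and GC trends removed (0.303), nor immediate early genes with the replicate block (0.0716). The cell cycle list rose by a mean of 0.62 on the log2 scale and the glycolysis list by 0.45. The list of dendritic cell markers and major histocompatibility complex (MHC) class II genes, which present antigen in dendritic cells, B cells and macrophages, was also higher, with a mean of 2.29. Genes of the T cell receptor complex, of cytotoxicity and of exhaustion did not move as lists. Camera placed 8 of 29 lists past an adjusted p of 0.05, 7 of them higher and 1 lower. With an estimated correlation it placed 0 lists past it (adjusted p between 0.655 and 0.917), a setting in which few residual degrees of freedom let few lists pass. Fry placed 2 lists past it, the cell cycle list and CD4 and regulatory T cell markers.

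No gene passed the test alone. With edgeR's quasi-likelihood test 0 genes were higher and 0 lower, the smallest adjusted p being 0.227. At an unadjusted p under 0.05 there were 499 higher and 386 lower genes, 885 in all where 578 would be expected by chance. Limma-voom also called 0 genes, while DESeq2 called 487 higher and 348 lower, of which 341 (40.8%) had a library with at most 3 counts. Of the DESeq2 calls 373 had a mean of at least 30 CPM, so they were not confined to near-empty genes. Without JAML-positive replicate B, edgeR called 10 higher genes and 1 lower, which was Malat1, and 0 without any of the other libraries. Groups did not overlap for 4449 genes (38.5%), where chance gives 33.3%. The median standard error of a log2 fold change was 0.56, and 0.26 for the 2252 genes above 100 CPM.

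The genes with the smallest p included Mpeg1, which encodes the pore-forming protein perforin-2 of phagocytes. Mpeg1 (chromosome 19, 12460770 to 12465285) lay at 10.7 ± 4.50 CPM in JAML-negative and 104 ± 20.8 CPM in JAML-positive cells, a log2 fold change of 3.28 (SE 0.49, adjusted p = 0.227). Jchain (chromosome 5, 88519809 to 88527897), the joining chain of secreted antibodies, was at 2.45 ± 3.0 and 74.8 ± 33.6 CPM (4.90, SE 0.82, adjusted p = 0.238). The fold change of Jchain was 7.80 without JAML-negative replicate A. With edgeR both passed under the filter of at least 30 CPM (adjusted p = 0.0117 for Mpeg1 and 0.0155 for Jchain), chosen after the data were seen, and with no filter on low counts (0.0234 for both). Both also passed with DESeq2. They did not pass with at least 5 CPM (0.0622 and 0.0672), with limma-voom (0.761 for both) or with a library left out (0.0587 to 0.881). Siglech (chromosome 7, 55768154 to 55779448), a lectin of plasmacytoid dendritic cells, was at 3.09 ± 3.70 and 52.6 ± 5.35 CPM (4.07, SE 0.79). Its counts in JAML-negative replicates A and B were 161 and 13, so the size of its fold change depends on the library used. Cdca3 and Kif22, which act in mitosis, had log2 fold changes of 2.43 (SE 0.44) and 1.79 (SE 0.37). In the other direction, the non-coding RNA AI504432 was at 193 ± 4.96 CPM in JAML-negative and 71.9 ± 3.31 CPM in JAML-positive cells (-1.43, SE 0.27). Rc3h1, which encodes the RNA-binding protein roquin-1, had a log2 fold change of -1.33 (SE 0.28). Top3b, Gga3 and Slc12a7 had values of -2.53 (SE 0.57), -1.90 (SE 0.46) and -1.10 (SE 0.27). These 8 genes had edgeR adjusted p between 0.477 and 0.609.

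Of the 35 cell cycle genes, 33 had higher values in JAML-positive cells and 2 lower. Birc5, which encodes survivin, went from 57.4 ± 3.25 to 130 ± 18.3 CPM (log2 fold change 1.18, SE 0.32). Cdk1, the kinase that drives entry into mitosis, went from 51.5 ± 0.581 to 105 ± 11.5 CPM (1.02, SE 0.33), and Kif11, a spindle motor, from 144 ± 2.83 to 240 ± 26.1 CPM (0.74, SE 0.24). An unadjusted p under 0.05 was found for 15 members, and 0 members passed over all genes or adjusted over the list alone. The list passed camera (adjusted p = 1.02e-05) and fry (adjusted p = 0.0347), and had adjusted p = 0.655 with an estimated correlation. It stayed past the threshold with any 1 library left out, at list means of 0.57 to 0.67. The dendritic cell and MHC class II list was higher in the same libraries, with a mean of 2.29.

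For glycolysis, 16 of 18 genes had higher values and 2 lower. Over all genes 0 members passed, and 4 did adjusted over the list alone, each with an adjusted p of 0.0417. These were Hk2 (log2 fold change 1.69, SE 0.46), Pgk1 (0.73, SE 0.21), Ldha (0.69, SE 0.21) and Aldoa (0.74, SE 0.24), enzymes from the first phosphorylation of glucose to the formation of lactate. Camera gave an adjusted p of 0.0161, and adjusted p = 0.688 with an estimated correlation. Fry gave the list an adjusted p of 0.0868. The list did not pass without JAML-negative replicate A (adjusted p = 0.133), without JAML-negative replicate B (0.0628) or without JAML-positive replicate A (0.0680), at means of 0.42, 0.48 and 0.39. The libraries with higher glycolysis values were also those with higher values of the dendritic cell and MHC class II list (mean 2.29).

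Among 34 genes of oxidative phosphorylation, 29 had higher values and 5 lower, with a list mean of 0.57 (camera adjusted p = 0.0124, and adjusted p = 0.850 with an estimated correlation). Cox7a2, a subunit of cytochrome c oxidase, had a log2 fold change of 1.37 (SE 0.44), Ndufv1 of complex I 0.97 (SE 0.39) and Atp5b of ATP synthase 0.45 (SE 0.21). Fry gave the list an adjusted p of 0.413. Members that passed numbered 0 over all genes and 0 adjusted over the list alone. The mean was 0.28 without JAML-positive replicate A (adjusted p = 0.613) and 0.37 without JAML-negative replicate B (adjusted p = 0.147). The list also differed between replicates A and B, lower in B by a mean of 0.51 (adjusted p = 0.0294). Fold changes were lower for longer transcripts across genes, from a median of 0.37 for genes under 1000 nucleotides to -0.25 for genes over 8000. After removal of the trends with length and GC content the list's mean was 0.33 (adjusted p = 0.303). Ribosomal protein genes, which are short, were higher in 76 of 78 cases (mean 0.25, camera adjusted p = 0.0677, and adjusted p = 0.917 with an estimated correlation). They passed as higher with limma-voom (adjusted p = 1.37e-05), with at least 5 CPM (0.0121), with at least 30 CPM (3.87e-04) and without JAML-positive replicate B (mean 0.66, adjusted p = 1.22e-11). Without JAML-positive replicate A they passed as lower (-0.17, adjusted p = 0.00105), and with length and GC trends removed the mean was -0.04 (adjusted p = 0.371). Rpl35 had a log2 fold change of 0.74 (SE 0.27). All 12 mitochondrially encoded genes had higher values, with a median of 0.14 but a mean of 0.57 (adjusted p = 0.152), and a mean of 0.18 among genes of at least 30 CPM. ND3, with 2 and 13 counts in JAML-negative cells, had a log2 fold change of 3.75, and ND6 of 0.68 (SE 0.27). The mitochondrial share of counts was 2.72% and 2.76% in JAML-negative and 2.94% and 2.92% in JAML-positive libraries. Of both lists 0 members passed over all genes or adjusted over the list alone.

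**Figure D2:**
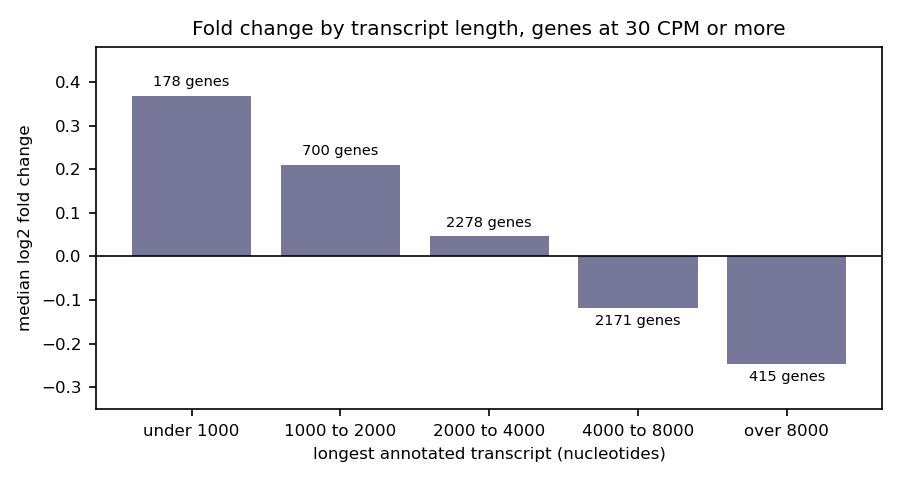
Median log2 fold change (JAML-positive over JAML-negative) of genes with a mean of at least 30 CPM, in 5 classes of longest annotated transcript in nucleotides. The number of genes stands at each bar. The medians run from 0.37 for 178 genes under 1000 nucleotides to -0.25 for 415 genes over 8000.

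Of 23 immediate early and AP-1 genes, which are induced within minutes of receptor stimulation, 18 had lower values in JAML-positive cells and 5 higher, with a list mean of -0.22. Egr1 went from 210 ± 4.83 to 134 ± 1.18 CPM (log2 fold change -0.65, SE 0.24). Fosb (-0.53, SE 0.24), Myc (-0.67, SE 0.29) and Zfp36 (-0.48, SE 0.21) had values in the same direction. Camera gave an adjusted p of 0.0405, but 0.0716 with the replicate block, 0.688 with an estimated correlation and 0.286 with fry, and 0 members passed over all genes or adjusted over the list alone. The list did not pass without JAML-negative replicate A (adjusted p = 0.200), JAML-negative replicate B (0.110) or JAML-positive replicate A (0.135), with means of -0.20, -0.24 and -0.10. The mean was -0.34 without JAML-positive replicate B, when the group was represented by replicate A, the library with 11.57% ribosomal protein counts. Heat shock and dissociation stress genes, which can be induced by tissue handling, were 7 higher and 7 lower (mean -0.04, adjusted p = 0.737). Gadd45b of that list had a log2 fold change of -0.70 (SE 0.32), and 0 members passed over all genes or adjusted over the list alone.

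**Figure D3:**
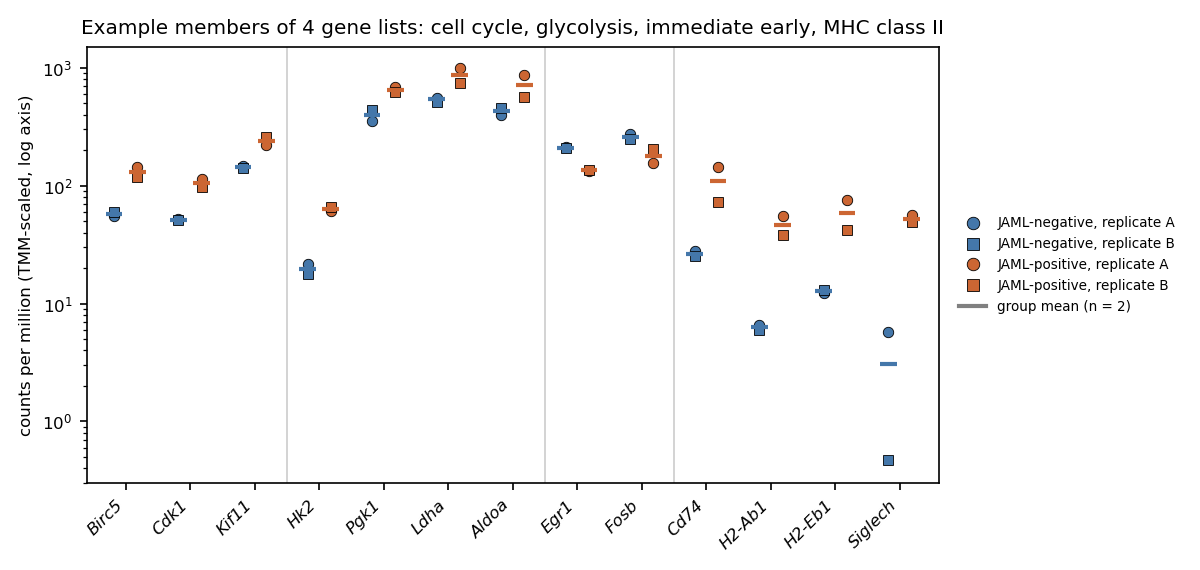
Expression in CPM (log axis) in each library of members of the cell cycle, glycolysis, immediate early and MHC class II lists, in that order from left to right. Circles and squares are replicates A and B, and bars are group means (n = 2). Cdk1 lay at means of 51.5 and 105 CPM, Egr1 at 210 and 134 CPM, and Cd74 at 26.4 and 109 CPM in JAML-negative and JAML-positive cells.

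The lists that describe T cell states did not pass with the settings chosen first. In the naive, stem-like and memory list 16 of 20 genes had lower values in JAML-positive cells (mean -0.13, camera adjusted p = 0.0938). It passed with limma-voom (mean -0.13, adjusted p = 0.00205), without JAML-positive replicate B (mean -0.19, adjusted p = 0.0414) and with at least 30 CPM (mean -0.31, adjusted p = 0.00720). Its adjusted p was 0.0885 to 0.688 in the other alternatives. Tcf7, the transcription factor of stem-like CD8 T cells, had a log2 fold change of -0.53 (SE 0.19), Bcl2 -0.71 (SE 0.22), Slamf6 -0.76 (SE 0.27) and S1pr1, the receptor for egress from tissue, -0.55 (SE 0.23). With length and GC trends removed the mean of the list was -0.11 (adjusted p = 0.163), and without JAML-positive replicate A it was -0.08 (adjusted p = 0.145). Cytotoxic and effector genes went both ways, 15 higher and 11 lower (mean 0.05, adjusted p = 0.821). Prf1, which encodes perforin, had a log2 fold change of 0.997 (SE 0.30), Gzmb, a granzyme, 0.62 (SE 0.20), the chemokine gene Xcl1 1.27 (SE 0.44) and Ccl5 -0.72 (SE 0.22). Inhibitory receptors and exhaustion genes were 9 higher and 12 lower, and their mean (0.21) and median (-0.10) differed in sign, with camera directed downwards (adjusted p = 0.821). Havcr2 and Ctla4, which encode TIM-3 and CTLA-4, had log2 fold changes of 1.11 (SE 0.37) and 0.56 (SE 0.23), and Nr4a1 and Vsir -0.58 (SE 0.21) and -0.55 (SE 0.23). In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. Costimulatory genes were 10 higher and 7 lower (adjusted p = 0.821), with Tnfrsf9, which encodes 4-1BB, at a log2 fold change of 0.90 (SE 0.33). T cell receptor complex and proximal signalling genes were 11 higher and 12 lower (mean -0.01, adjusted p = 0.737), with Plcg1 at -0.59 (SE 0.22). Interleukin-2 and common gamma chain signalling genes were 5 higher and 16 lower (mean -0.25, adjusted p = 0.0980, 0.0359 with limma-voom and 0.655 with an estimated correlation), with Il2ra at 1.13 (SE 0.40). The mean of that list was -0.52 without JAML-negative replicate A and -0.50 without JAML-positive replicate A. PI3K-AKT-mTOR pathway genes were 10 higher and 16 lower (adjusted p = 0.391), with Rictor at -0.98 (SE 0.26). Chemokine receptors and adhesion molecules were 7 higher and 11 lower (adjusted p = 0.340), with Itgax at -0.82 (SE 0.31). Tissue residency genes were 10 higher and 7 lower (adjusted p = 0.875), and Ccr8, without counts in JAML-negative cells, was at least 70.3-fold higher at 279 and 143 counts in JAML-positive replicates A and B. Over all genes and adjusted over the list alone, 0 members of these 6 lists passed.

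**Figure D4:**
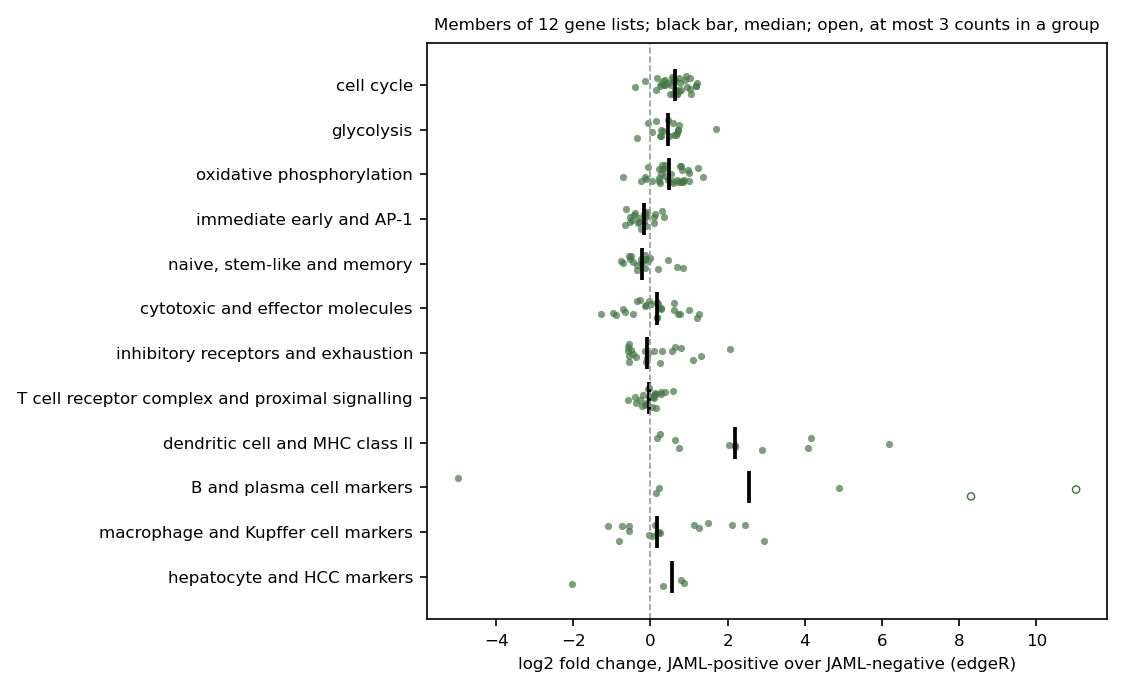
Log2 fold change (JAML-positive over JAML-negative, edgeR) of the tested members of 12 gene lists. Each point is a gene, black bars are list medians, and open points are genes with at most 3 counts in a group. Medians were 0.63 for the cell cycle, 0.46 for glycolysis and 2.19 for the dendritic cell and MHC class II list, and -0.03 for the T cell receptor list.

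Some lists of markers of other cell types also had higher values in JAML-positive cells by camera with the preset correlation, and none with an estimated correlation. All 11 tested genes of the dendritic cell and MHC class II list had higher values in JAML-positive cells, with 0 passing over all genes and 5 adjusted over the list alone. Cd74, the invariant chain, went from 26.4 ± 1.83 to 109 ± 51.2 CPM (log2 fold change 2.03, SE 0.45), H2-Ab1 from 6.29 ± 0.468 to 46.7 ± 11.8 CPM (2.88, SE 0.66) and H2-Eb1 from 12.7 ± 0.611 to 58.9 ± 24.1 CPM (2.20, SE 0.57). The list passed camera (adjusted p = 5.38e-05, and adjusted p = 0.655 with an estimated correlation) and stayed past the threshold with any 1 library left out, at means of 2.10 to 2.84. Fry gave it an adjusted p of 0.158. Of the B and plasma cell list 6 of 12 genes in the table were tested, and 5 of these 6 were higher (mean 2.34, adjusted p = 0.0677, and adjusted p = 0.655 with an estimated correlation). Jchain alone passed adjusted over the list. The lower gene was Fcer2a, with 248 and 125 counts in JAML-negative replicates A and B, and 0 and 12 in JAML-positive replicates A and B. Its log2 fold change was -4.98 (SE 2.28). That list passed with at least 5 CPM (mean 3.27, adjusted p = 0.0121) and without JAML-positive replicate B (mean 3.25, adjusted p = 0.0115). Mzb1 had no counts in JAML-negative cells and was at least 84.2-fold higher by counting error alone. Ms4a1, with 1 count in JAML-negative cells, had a count ratio of 392 (95% counting interval 70.0 to 15538). The 95% intervals from edgeR began at 2.96-fold for Mzb1 and 1.21-fold for Ms4a1. For Mzb1 that end is approximate, since a fold change from 0 counts is finite only with an added count.

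Markers near the detection floor formed 3 further lists that rose by camera. A low marker can enter the test through the libraries of 1 group alone. Genes above 10 counts numbered 10855 and 10771 in JAML-negative replicates A and B, and 11592 and 11490 in JAML-positive replicates A and B. Endothelial markers were 7 higher and 3 lower (mean 2.14, adjusted p = 0.0161, and adjusted p = 0.655 with an estimated correlation), at a median of 2.82 CPM, among them Kdr (log2 fold change 3.94, SE 1.86) and Flt4 (5.89, SE 2.60). Of 12 neutrophil and monocyte markers in the table only 4 were tested, and all 4 were higher (mean 2.05, adjusted p = 0.0161, and adjusted p = 0.655 with an estimated correlation). Their median was 1.72 CPM, with Mmp9 at a log2 fold change of 1.84 (SE 1.07). Erythroid and platelet markers were 3 higher and 1 lower (mean 4.18, adjusted p = 0.0405, 0.0562 with the replicate block and 0.688 with an estimated correlation). The median fold change of that list was 4.59, and 3.71 with genes without counts set at their bound. Hbb-bs was at least 166-fold higher by counting error alone, and Hba-a1, with 1 count in JAML-negative cells, had a count ratio of 695 (95% counting interval 124 to 27488). The 95% intervals from edgeR began at 17.1-fold for Hbb-bs and 4.37-fold for Hba-a1. For Hbb-bs, with 0 counts in JAML-negative cells, that end is approximate for the reason given for Mzb1. With any library left out none of these 3 lists passed, the lowest adjusted p being 0.0533, and the mean of the neutrophil list was 0.90 without JAML-positive replicate A and 0.96 without JAML-negative replicate B. None passed with limma-voom (adjusted p between 0.331 and 0.453), nor the neutrophil list with no filter on low counts (mean 0.58, adjusted p = 0.537). Members that passed adjusted over the list alone numbered 0 for the endothelial and neutrophil lists and 2 for the erythroid list, and 0 over all genes.

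Other marker lists did not pass camera with the settings chosen first. Macrophage and Kupffer cell markers were 11 higher and 6 lower (mean 0.26, adjusted p = 0.875), with Clec4f at a log2 fold change of 2.95 (SE 1.70). Their mean was 0.13 without JAML-negative replicate B or JAML-positive replicate A, and 0.40 without JAML-negative replicate A. Hepatocyte and carcinoma markers, with 4 tested of 16 in the table, were 3 higher and 1 lower. They had a median of 0.55 but a mean of -0.22, with camera directed downwards (adjusted p = 0.821). They passed as lower without JAML-negative replicate B (mean -1.50, adjusted p = 0.0355). Afp, which encodes alpha-fetoprotein, went from 22.5 ± 1.09 to 5.36 ± 2.55 CPM (-2.03, SE 0.83). NK cell and ILC1 markers were 7 higher and 8 lower, with a median of -0.06 and a mean of 1.02 (adjusted p = 0.697). Klra4 was at least 123-fold higher from 0 counts in JAML-negative cells, Irf8 had a log2 fold change of 1.19 (SE 0.38) and Klre1 -1.02 (SE 0.46). CD4 and regulatory T cell markers were 10 higher and 4 lower (mean 1.17, camera adjusted p = 0.0677, fry adjusted p = 0.0347, and 0.655 with an estimated correlation), with Cd40lg at 4.24 (SE 1.25) and Ikzf2 at -0.89 (SE 0.36). Counts of Cd40lg were 1 and 70 in JAML-negative replicates A and B, and 356 and 1048 in JAML-positive replicates A and B. Gamma-delta and IL-17 T cell markers were 1 higher and 3 lower (adjusted p = 0.420), with Cd163l1 at -1.38 (SE 0.79). Stellate cell and fibroblast markers, with 3 tested of 7 in the table, were 3 of 3 higher (mean 1.26, adjusted p = 0.698), with Col1a1 at 0.70 (SE 1.26). Their mean was 2.73 without JAML-negative replicate A, 2.55 without JAML-positive replicate B and 0.81 without JAML-negative replicate B. Over all genes and adjusted over the list alone, 0 members of these 6 lists passed.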

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

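The filter of at least 30 CPM and the removal of length and GC trends were chosen after the data were seen. Spread was widest among low genes: the median standard error of a log2 fold change was 2.0 for genes up to 3 CPM and 0.26 above 100 CPM. Scaling moved the median fold change of all genes by at most 0.03 in size (-0.03 with library totals only) and left 8 lists and 0 genes past the threshold. The fold change of Jaml kept its sign and stayed short of the threshold in 14 of 14 alternatives (0.07 to 0.28). DESeq2 called 487 higher and 348 lower genes, and 311 of its calls had at most 3 counts in a group. Of its calls 373 had a mean of at least 30 CPM. Among the other 76 genes named here, Fcer2a left out, DESeq2 called 54. No filter on low counts gave 2 higher genes and the filter of at least 30 CPM gave 2, Mpeg1 and Jchain in both. Leaving out a library gave 0 to 10 higher genes, 0 to 1 lower genes and 3 to 8 lists. The 10 higher genes and 1 lower gene came without JAML-positive replicate B, when JAML-positive replicate A stood alone for its group, and Gzmb, Rpl35 and Malat1 were among them. An estimated correlation gave 0 lists past the threshold, in a setting whose few residual degrees of freedom let few lists pass. Fry gave 2, the cell cycle list and CD4 and regulatory T cell markers, which missed it with camera (0.0677). Apart from that limit of the estimated correlation, the cause of these differences in calls was not tested.

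The letters A and B gave a correlation across genes of 0.018 between the A minus B differences of the 2 groups. No effect shared by letter was therefore seen across genes. Whether libraries of the same letter share an animal, pool or sort is not settled by this value. The replicate block gave 0 higher and 0 lower genes and 6 lists, with the immediate early list at adjusted p = 0.0716 and the erythroid list at 0.0562.

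The 8 lists past the threshold kept their direction in all 115 values from alternatives, of which 43 missed the threshold. Among the other 21 lists 14 never changed sign. With an estimated correlation, fry and the replicate block, a list's mean is that of the main fit by construction. Its sign could not change in those settings, which are counted here. With libraries left out in turn, list means ran from -0.14 to 2.05 for gamma-delta markers, -2.18 to 1.04 for hepatocyte markers, -0.27 to 0.36 for cytotoxic genes, -0.17 to 0.66 for ribosomal proteins and -0.0307 to 0.00276 for T cell receptor genes. Fold changes ran from -0.0644 to 0.173 for Cd3e, -0.0908 to 0.0394 for Cd8a and -0.27 to 7.54 for Col1a1. The T cell receptor list was at 9.1e-05 with upper quartile factors, and gamma-delta markers at 0.68 with no filter on low counts. With at least 30 CPM the interferon list was at -0.0389 and NK cell markers at -0.273. With length and GC trends removed, cytotoxic genes were at -0.202, ribosomal proteins at -0.0375, Cd8b1 at -0.0275 and Cd3e at -0.0596, each with the opposite sign. The cause was not tested.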

Other observations

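Tests of the deposited pathway annotation, of macrophage markers, and the removal of length and GC trends were chosen after the result was seen. Of 999 KEGG and Reactome terms, 89 were higher and 0 lower by camera at an adjusted p under 0.05, terms of DNA replication and energy metabolism among them, and 0 terms passed with an estimated correlation (adjusted p = 0.955 for the 3 terms below). S Phase had 139 tested genes with a mean log2 difference of 0.49 (adjusted p = 0.00552), KEGG oxidative phosphorylation 113 genes at 0.60 (adjusted p = 0.00552) and the proteasome, which degrades tagged proteins, 45 genes at 0.45 (adjusted p = 0.00599). The terms share many genes. After the trends with length and GC content were removed 0 terms passed, and these 3 had means of 0.42, 0.37 and 0.28 (adjusted p = 0.139, 0.602 and 0.371), so S Phase lost its call while its mean stayed near its size, for a reason not tested. The fixed cell cycle list still passed after that removal. Ribosomal protein genes and other short transcripts were higher in JAML-positive replicate A, where expression relative to the gene mean fell with transcript length (Spearman's rho across genes -0.28, against 0.04 to 0.09 in the other libraries).

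Of the fixed lists not yet described, fatty acid oxidation had 11 higher and 7 lower genes (mean 0.43, median 0.15, camera adjusted p = 0.598), and a mean of 0.0792 among genes of at least 30 CPM. Eci1, which encodes an enoyl-CoA isomerase, had 1 count in each JAML-negative library and 348 and 461 in JAML-positive replicates A and B. Its count ratio was 391 (95% counting interval 108 to 3234), while its 95% interval from edgeR began at 5.80-fold. Type I interferon response genes were 13 higher and 10 lower (mean 0.42, median 0.03, camera adjusted p = 0.875), with Ifi27l2a at a log2 fold change of 1.37 (SE 0.53). Neither list had a member past the threshold over all genes or adjusted over the list alone.

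The 4 libraries can be split into equal groups in 3 ways, too few for a share under 0.05. The real split gave 885 genes at an unadjusted edgeR p under 0.05 and 8 lists by camera, against 397 genes and 3 lists for A against B and 400 genes and 1 list, ribosomal proteins, for the crossed split. The 3 lists of A against B were ribosomal proteins, stellate cell markers and oxidative phosphorylation, the last lower in replicates B by a mean of 0.51 (adjusted p = 0.0294), near the 0.57 of the real split.

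In 612 genes a library had at most 3 counts while each of the other 3 had more than 100. JAML-negative replicates A and B lacked 193 and 212 of them, and JAML-positive replicates A and B 94 and 113. Counting noise at this depth predicts 0 such genes. Genes with at most 3 counts in 1 library of a pair and more than 100 in the other numbered 1673 in the JAML-negative pair, 1189 in the JAML-positive pair and 1302 to 1597 between groups. Why these transcripts are nearly absent from 1 library, more often a JAML-negative one, was not tested. Technical loss and real differences between samples cannot be told apart here. Large fold changes of genes at 0 in a group may partly come from the same pattern.

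The dendritic cell and MHC class II list was higher in the libraries labelled JAML-positive by camera (adjusted p = 5.38e-05). It did not pass with an estimated correlation (adjusted p = 0.655) or with fry (0.158). Its median of 2.19 was at percentile 100 of random lists of equal abundance, against more low-abundance genes detected in those libraries as the whole cause. Macrophages or Kupffer cells stay open, since their markers had an upper quartile of 1.27 but a median of 3.72 CPM, and plasma cells too: the added markers had a median of 0.0975, but 6 of 7 were at 10 CPM or more in both JAML-negative libraries, which would hide a small share, and Jchain and Mzb1, outside the added list, had higher values (adjusted p = 0.238 and 0.609). The added markers of plasmacytoid dendritic cells had a median of 1.14, higher in 13 of 14 genes and at percentile 99.99 of random lists. Tcf4 went from 100 and 8 to 557 and 980 counts, Blnk from 12 and 3 to 385 and 375, Cybb from 689 and 238 to 1113 and 1467, and Spib from 1 and 0 to 582 and 83, while 5 of the 14 genes were at 10 CPM or more in both JAML-negative libraries. A hypothesis is that the JAML-positive sort may hold some plasmacytoid dendritic cells or their RNA, although the cells were sorted as CD8 T cells. Whether the gate excludes plasmacytoid dendritic cells was not tested, nor was expression of class II genes by the T cells themselves. B cells, which also present antigen with class II genes, were not tested as a source. The B and plasma cell list had a mean of 2.34 (camera adjusted p = 0.0677). Ms4a1 of that list went from 1 and 0 to 304 and 102 counts, but Fcer2a from 248 and 125 to 0 and 12. These values do not settle which cell type is the source.

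The cell cycle, glycolysis and oxidative phosphorylation lists were higher in the libraries labelled JAML-positive. After the trends with transcript length and GC content were removed, camera's adjusted p was 1.20e-05 for the cell cycle list (mean 0.62 before and 0.60 after) and 0.0175 for glycolysis (0.45 and 0.46), which argues against these trends as the whole cause. The oxidative phosphorylation list lost its call, at adjusted p = 0.303, and its mean went from 0.57 to 0.33, so length or GC content, removed together, may account for part of it. The medians of all 3 lists were at percentile 100 of random lists of equal abundance, as was that of ribosomal proteins. More low-abundance genes detected in the JAML-positive libraries could hardly be the whole cause in any case. Of the members, 34 of 35, 18 of 18 and 33 of 34 were at 10 CPM or more in both JAML-negative libraries. More dividing cells among JAML-positive T cells stay a hypothesis, since dividing cells of another type in the sort were not tested. With an estimated correlation camera did not call the cell cycle list (adjusted p = 0.655), glycolysis (0.688) or oxidative phosphorylation (0.850). For the cell cycle list, with an estimated correlation of -0.02, that setting cannot decide the question, because its few residual degrees of freedom let few lists pass. For glycolysis and oxidative phosphorylation the estimated correlations were 0.12 and 0.43, above the preset 0.01, so the preset may be too small for them. Fry did not call glycolysis (adjusted p = 0.0868) or oxidative phosphorylation (0.413), but called the cell cycle list (0.0347).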
